A study of Homo sapiens with 10 samples.

How the data were processed

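Chromatin immunoprecipitation (IP) against the HA epitope tag was measured on NimbleGen promoter tiling arrays in LNCaP cells, an established human prostate cancer line. The 10 samples were 5 biological replicates, each hybridised to 2 array designs that together tile the promoters. HA-SOX4 had 3 replicates, from cells infected with a lentivirus for HA-tagged SOX4 and YFP, and YFP had 2, from cells infected with the YFP virus alone. Every array carried an IP and the input DNA of the same cells in different dyes. The labels call the samples biological replicates without saying whether the cultures were separate, so p-values measured the spread between these IPs.

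The 20 scanner files held probe intensity as extracted by NimbleScan, per the file headers, in version 2.3.22 for both YFP replicates and HA-SOX4 replicates 1 and 2 and version 2.3.78 for HA-SOX4 replicate 3. Per the file headers, coordinates followed build HG18, and those headers recorded no background subtraction or normalisation of the intensity values. The authors also deposited a processed score per probe. Each column of that score was an exact linear rescaling (r = 1) of the log2 ratio of the file named IP over the file named input, with an SD near 1 and column medians from -0.11 to 0.21. The rescaling left the scale of that score unstated, while its direction followed the file names.

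The dye direction was not settled by the sources. Per the labels, the IP was in Cy5 on every array. Per the file headers, the files named IP came from the 532 nm image, that of Cy3, for both YFP replicates and HA-SOX4 replicates 1 and 2, and from the 635 nm image, that of Cy5, only for HA-SOX4 replicate 3. The ratios here took IP and input from the file names, the direction that the authors' deposited score also has. That score is an exact rescaling of the same named files, so it does not show separately which dye held the IP. This direction is therefore not certain. If the dyes of the labels held instead, the signs of both YFP replicates and of HA-SOX4 replicates 1 and 2 would turn. For YFP replicate 2, the files of its 2 samples held the other array design than their titles state, per the file headers, and were joined by probe identifier. HA-SOX4 replicate 3 differed from the rest in NimbleScan version and, by the file names but not by the labels, in dye orientation. It was treated as a technical batch of its own, so comparisons were also made within the other 4 replicates.

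From the intensities, log2(IP/input) was computed for 757904 genomic probes in 23047 tiled regions and centred on the median of each array, with no loess or quantile step. Random control probes, 10000 to 10364 per array, were left out of the ratios. Signal over background was described as the percent of probes brighter than the 95th percentile of the random probes. The number of arrays limits the precision. Probes within 300 bp of a central probe in the same tiled region were averaged, with at least 3 probes per window, which gave 730176 overlapping windows in 23039 regions. The arrays of a replicate were stacked into a single column. HA-SOX4 was compared with YFP, and each group with its input, in a linear model with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all windows and a threshold of 0.05. Tables were handled with the data.table package (version 1.17.8), matrixStats 1.5.0, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

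Peaks per replicate were windows whose median log2 ratio exceeded the smallest cutoff at which windows below the mirrored cutoff numbered at most 5% of those above it. Overlapping windows were merged, and peaks overlapping by at least 1 bp counted as shared. The overlap between replicates was also counted among the 500 tiled regions per array design with the highest window of each replicate. This count, the comparisons of HA-SOX4 replicates 1 and 2 with replicate 3, and the alternatives of dye direction, array design and whole-region means were chosen after the data were examined, whereas the tests, the rule for named regions and the list of alternatives were otherwise fixed before the data were examined.

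The model was tested on independently simulated windows with the spread of the data and known shifts in all 3 HA-SOX4 replicates. The same run held 50 windows at each shift of 1, 2, 4 and 8 and gave 3 false calls among unshifted windows. Of 50 windows shifted by 4 on the log2 scale among 730176, 4% were called, and of 50 shifted by 8, 80% were called. No window shifted by 1 or 2 was called. With 1000 windows shifted by 4, 60.2% were called with 25 false calls, and with 20000 shifted by 4, 92.8% were called with 960 false calls. The measured windows overlap, and HA-SOX4 replicate 3 did not follow replicates 1 and 2. These shares therefore do not give the power to call a shift present in replicates 1 and 2 alone.

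The rule for named regions took tiled regions called at the threshold first. Because none was called, it took the regions with the smallest p among those where every HA-SOX4 replicate lay above every YFP replicate, at most 5, by position. Regions chosen otherwise are said to have been chosen after their values were seen. The files identify tiled regions by HG18 position and do not pair them with gene names, and the annotation used here is on another build. The planned tests of gene lists, of named genes and of the SOX motif were therefore not run. Alternatives covered normexp background correction, loess, quantile normalisation, scaling, centring, the deposited score, window size and statistic, probe filters, eBayes settings, array weights, thresholds, a replicate block, the input or IP channel alone, dye direction, array design and each replicate left out.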

Results

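SOX4 is an HMG-box transcription factor, and the question addressed was where HA-tagged SOX4 bound promoter DNA in LNCaP prostate cancer cells. Anti-HA IP was set against input DNA in 3 HA-SOX4 replicates and in 2 replicates of cells with YFP alone, which carry no HA tag and give the background of the antibody. The arrays tiled 23047 regions with a median length of 4261 bp and a mean of 32.9 probes, and 63.6% of the regions were 4250 to 4300 bp long. All values below are centred log2(IP/input), with IP and input taken from the file names. With the dyes stated in the labels, the signs of both YFP replicates and of HA-SOX4 replicates 1 and 2 would be turned.

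Signal over background differed between replicates. In HA-SOX4 replicate 2, with IP taken from the file names, 54.3% of probes on array design 1 and 63.4% on design 2 were brighter in the IP channel than the 95th percentile of random probes. The shares were 35.4% and 30.3% in HA-SOX4 replicate 1, 17.5% and 19.9% in HA-SOX4 replicate 3, 15.7% and 30.3% in YFP replicate 1, and 38.0% and 34.3% in YFP replicate 2. In the input files, which would be the IP of these 4 replicates with the dyes of the labels, the shares were 35.8% and 32.0% in HA-SOX4 replicate 1, 40.3% and 47.6% in HA-SOX4 replicate 2, 32.3% and 54.8% in YFP replicate 1, and 52.7% and 49.5% in YFP replicate 2. In the direction of the file names, HA-SOX4 replicates 1 and 2 had the widest upper tails on design 1. Their 99th percentile of window values was 3.44 and 2.39 on design 1, against 0.97 in HA-SOX4 replicate 3, 0.64 in YFP replicate 1 and 1.37 in YFP replicate 2. Turning the ratios to the dyes of the labels would make the lower tails the upper ones, with 1st percentiles on design 1 of -1.71 and -1.91 in HA-SOX4 replicates 1 and 2 and -1.77 and -1.96 in YFP replicates 1 and 2. On design 2 they were -2.41, -2.35, -2.70 and -1.82, so that the order by file names would not hold.

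**Figure D1:**
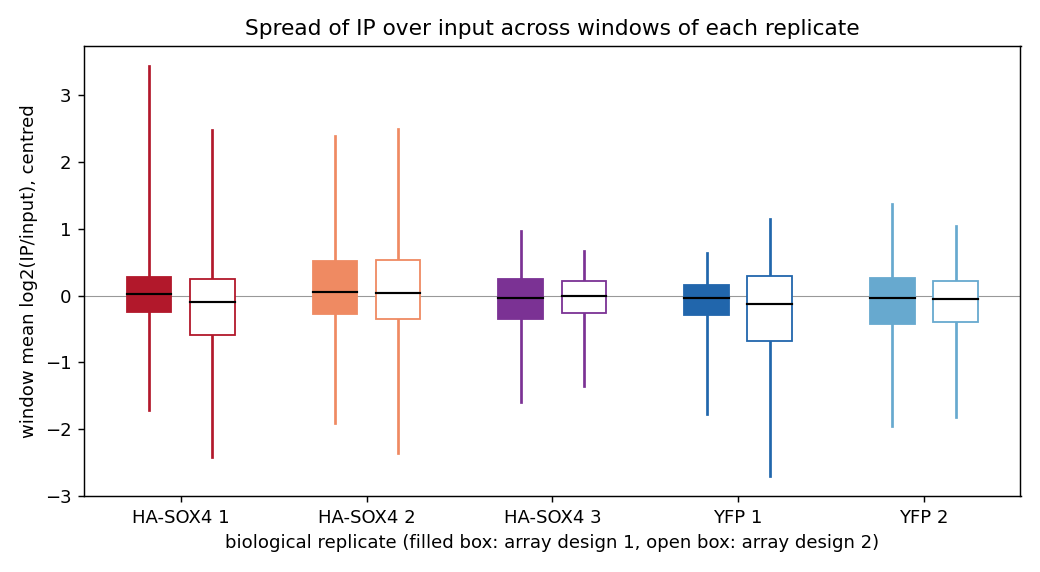
Distribution of window mean log2(IP/input), centred per array (y axis), in each biological replicate (x axis), with filled boxes for array design 1 and open boxes for design 2. Boxes span the 25th to 75th percentile with the median as a black line, and thin lines span the 1st to 99th; on design 1 the upper end was 3.44 in HA-SOX4 replicate 1 and 0.97 in HA-SOX4 replicate 3.

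The 5 regions taken by the rule, which looked only for HA-SOX4 above YFP, were places where the YFP IP lay below its input while the HA-SOX4 IP lay near its input. On chromosome 19 (region 2895180 to 2899431, window 2895180 to 2895480), HA-SOX4 averaged -0.37 ± 0.33 (SD, n = 3) while the YFP replicates were at -2.84 and -3.16, a difference of 2.63 with an SE of 0.32. On chromosome 4 (region 89837202 to 89841503, window 89839002 to 89839302), HA-SOX4 averaged 0.45 ± 0.56 (SD, n = 3) and YFP -2.70 ± 0.44 (SD, n = 2), a difference of 3.14 with an SE of 0.42. The windows in the regions on chromosome 11 (179579 to 187544), chromosome 7 (72046989 to 72051239) and chromosome 9 (139451825 to 139459222) differed by 2.40, 2.27 and 2.52, with HA-SOX4 means of 0.03, 0.07 and -0.13. None of these 5 regions passed the test (limma, adjusted p = 0.892 for each). With the IP channel alone and no input, the differences on chromosomes 19, 11 and 9 turned to -0.32, -0.21 and -0.086. Loess within arrays lowered the differences to 1.26 on chromosome 19, 1.19 on chromosome 11, 0.97 on chromosome 7, 1.14 on chromosome 9 and 1.64 on chromosome 4.

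Across the promoters, 0 of 730176 windows and 0 tiled regions differed between HA-SOX4 and YFP (limma, smallest adjusted p = 0.892). At an unadjusted p under 0.05, 13177 windows were higher and 8707 lower in HA-SOX4, both fewer than the 18254 per direction given by chance. The balance of these shares, 1.80% higher and 1.19% lower, turned to 1.24% and 2.41% with normexp, 0.248% and 1.68% with loess, 0.867% and 1.82% with quantile normalisation and 0.638% and 2.81% with trend and robust settings of eBayes. The tilt to higher grew to 7.70% and 2.62% with array weights, 7.14% and 1.47% with a replicate block, 3.75% and 1.59% with the deposited score and 2.60% and 0.572% with centring on the mode. Number 3 occurs only in HA-SOX4, so that replicate did not enter the difference in the replicate block. With the dyes of the labels the shares were 1.10% higher and 3.89% lower, for HA-SOX4 against input alone they were 0.959% and 5.78%, and with the IP channel alone 0.946% and 3.23%. Without HA-SOX4 replicate 1 the shares were 3.67% higher and 1.16% lower, and without HA-SOX4 replicate 3 they were 4.87% and 1.74%. Without YFP replicate 1 they were 0.386% higher and 0.797% lower, and without YFP replicate 2 they were 0.577% and 0.439%. All 3 HA-SOX4 replicates lay above both YFP replicates in 12.2% of windows and below both in 10.7%, where chance gives 10% each way. The mean over all probes of a region, an alternative chosen after the data were seen, also gave 0 of 23047 regions with limma, with 799 higher and 172 lower at an unadjusted p under 0.05. With the IP channel alone, 1814 windows in 555 regions were called, 5 higher and 1809 lower in HA-SOX4. Within the 4 replicates that share a dye orientation and a NimbleScan version, HA-SOX4 against YFP gave 0 called windows with limma (smallest adjusted p = 0.447), with 35559 higher and 12697 lower at an unadjusted p under 0.05. With the dyes of the labels these 4 would turn together, to 12697 higher and 35559 lower. The median SE of a difference over all 5 replicates was 0.36.

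Several promoters were high in HA-SOX4 replicates 1 and 2 and not in the third, and the following were chosen after their values were seen. On chromosome 8 (region 124095486 to 124099736, window 124097886 to 124098186), HA-SOX4 replicates 1 and 2 reached 5.78 and 4.53 while replicate 3 was at -0.22 and the YFP replicates at -1.01 and 0.03. On chromosome 19 (region 59073778 to 59078124, window 59075291 to 59075591) the values were 4.73 and 4.22 in HA-SOX4 replicates 1 and 2, -1.51 in replicate 3, and -2.65 and -1.27 in YFP. On chromosome 13 (region 27090502 to 27096039, window 27094202 to 27094602) they were 4.37, 4.16 and 0.16 in HA-SOX4 and -1.84 and -0.14 in YFP. The mean differences of these windows from YFP, 3.85, 4.44 and 3.88, had SEs of 1.69, 1.86 and 1.34, and none passed the test (limma, adjusted p = 0.892).

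Some promoters were high in YFP and not in HA-SOX4. They too were chosen after their values were seen, by smallest p, which favours a small spread, whereas the preceding ones were chosen by the height of HA-SOX4 replicates 1 and 2 over YFP. On chromosome 16 (region 79394845 to 79399176, window 79396864 to 79397305), the YFP replicates were at 3.98 and 4.05 and the HA-SOX4 replicates at 0.21, 0.14 and 0.16, a difference of -3.85 with an SE of 0.26. On chromosome 11 (region 72088309 to 72092559, window 72089709 to 72090009) YFP averaged 2.90 ± 0.14 (SD, n = 2) and HA-SOX4 -1.02 ± 0.40 (SD, n = 3). On chromosome 10 (region 115412996 to 115417295, window 115412996 to 115413196) YFP averaged 2.70 ± 0.08 (SD, n = 2) and HA-SOX4 -1.08 ± 0.31 (SD, n = 3). None passed the test (limma, adjusted p = 0.892 for each).

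**Figure D2:**
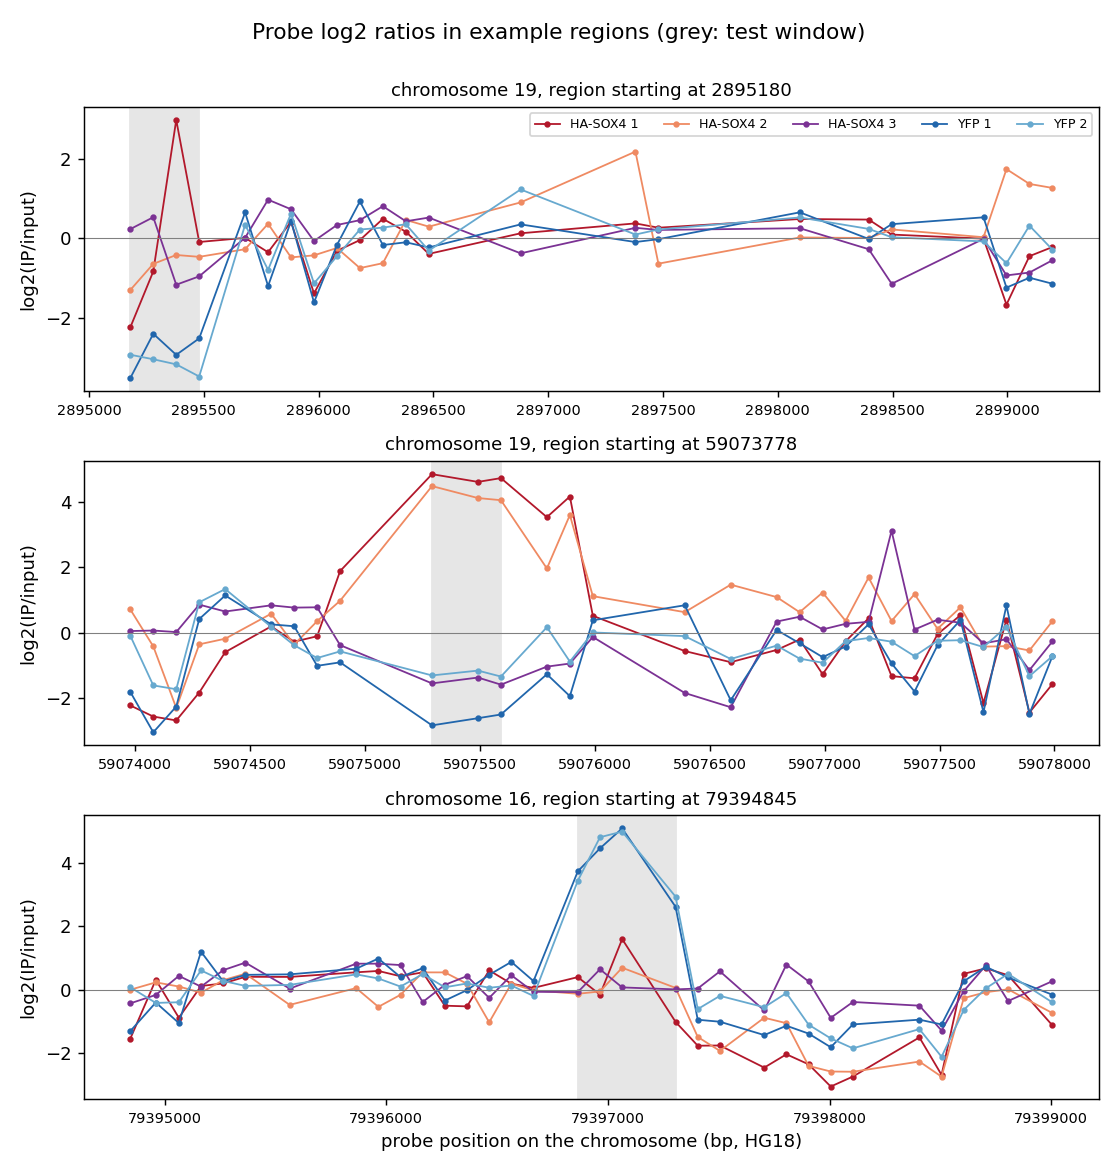
Centred log2(IP/input) of single probes (y axis) against HG18 position in bp (x axis) in 3 tiled regions, with a line and points for each of the 5 biological replicates and the tested window in grey. In the middle region the window means of HA-SOX4 replicates 1 and 2 were 4.73 and 4.22 and that of replicate 3 was -1.51, while in the lowest region the YFP replicates were at 3.98 and 4.05 and all HA-SOX4 replicates between 0.14 and 0.21.

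The question of which promoters were enriched over input was asked within each group. With all replicates, 0 windows were called in HA-SOX4 and 0 in YFP (limma, smallest adjusted p = 0.444 and 0.196). In the direction of the file names and at an unadjusted p under 0.05, 20674 windows were higher and 59593 lower than input in HA-SOX4. YFP had 21468 higher and 78530 lower. Turning HA-SOX4 replicate 3 alone, which mirrors the dyes of the labels, again called 0 windows in HA-SOX4 and 0 in YFP (limma, smallest adjusted p = 0.255 and 0.283). That turn changes the fit, so the unadjusted counts would not simply swap, and they were not made for that direction. Without HA-SOX4 replicate 3, 27671 windows were called in HA-SOX4 and 0 in YFP in the same limma model. The smallest adjusted p of that limma fit was 0.0426 in HA-SOX4 and 0.0658 in YFP, just on either side of the threshold. The 27671 against 0 therefore does not show that only HA-SOX4 departed from input. By the file names, 29419 YFP windows were higher and 106486 lower there at an unadjusted p under 0.05. With the dyes of the labels every replicate of that fit would turn, so 106486 would be higher and 29419 lower.

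Of those 27671 windows, 5531 in 1809 tiled regions were higher than input in HA-SOX4 replicates 1 and 2. Their medians were 1.90 and 1.70 in these replicates, -0.21 and 0.06 in YFP and -0.40 in HA-SOX4 replicate 3. The windows were selected on these 2 HA-SOX4 replicates, so their height over YFP is no separate test. HA-SOX4 replicate 3 was above 0 in 17.1% of these higher windows, against 48.4% of all windows. Both YFP replicates were above 0 in 22.3% of them, against 32.9% of all windows. The other 22140 windows, in 5204 regions, were lower than input, and both YFP replicates were below 0 in 98.6% of those, against 41.8% of all windows. HA-SOX4 replicate 3 was below 0 in 59.0% of the lower windows, against 51.6% of all windows. Among the higher regions with the largest mean relative to its SE, chosen after their values were seen, a window on chromosome 10 (42595964 to 42596364) averaged 3.36 with an SE of 0.18 in HA-SOX4 replicates 1 and 2. Windows on chromosome 9 (157483 to 157783) and chromosome 18 (22764655 to 22765255) averaged 3.30 and 2.99, with SEs of 0.20 and 0.19 (limma, adjusted p = 0.0426 for each of the 3). In YFP the windows on chromosomes 10, 9 and 18 averaged -0.24, -0.41 and -0.49, and in HA-SOX4 replicate 3 they were at -0.72, -2.02 and -0.72. The difference between HA-SOX4 replicates 1 and 2 and YFP did not itself pass the test for any window. With the dyes of the labels, all 4 replicates of this fit would turn, so the 22140 windows would be higher and the 5531 lower than input. HA-SOX4 replicate 3 would not turn. It would then lie on the other side from replicates 1 and 2 in 17.1% of the 5531 and 59.0% of the 22140.

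**Figure D3:**
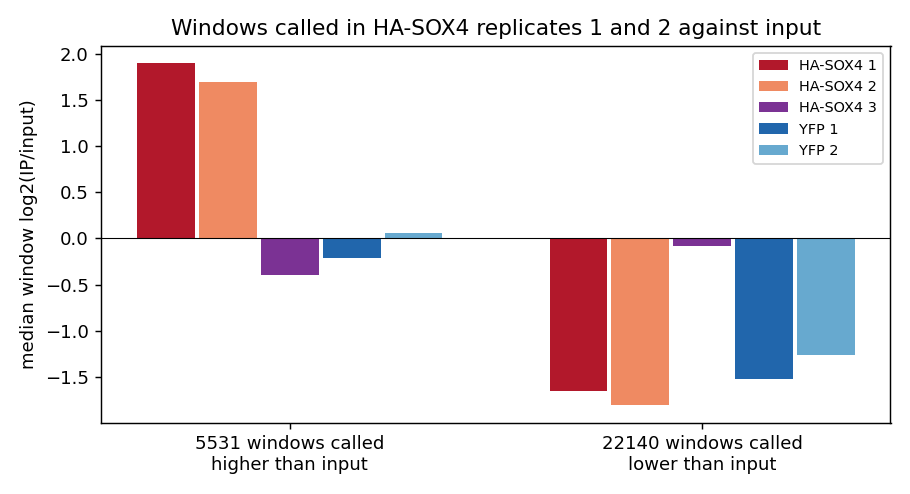
Bars give the median window log2(IP/input) (y axis), with IP and input from the file names, of each biological replicate in the windows called higher or lower than input from HA-SOX4 replicates 1 and 2 (x axis). In the 5531 higher windows the medians were 1.90 and 1.70 in these replicates, -0.40 in HA-SOX4 replicate 3 and -0.21 and 0.06 in YFP; the windows were selected on the first 2 bars.

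In the direction of the file names, the regions highest in each replicate overlapped within YFP and between HA-SOX4 replicates 1 and 2. Of the 500 highest regions per array design, the YFP replicates shared 160 on design 1 and 209 on design 2, where independent lists would share 21.9 and 21.5. HA-SOX4 replicates 1 and 2 shared 52 and 68, of which 44 and 63 were in neither YFP list. Each YFP list held 500 of 11413 regions on design 1 and 500 of 11626 on design 2, so most regions lie outside both. The 44 and 63 therefore show no specificity for HA-SOX4. HA-SOX4 replicate 3 shared 11 and 10 regions with replicate 1 and 18 and 13 with replicate 2. HA-SOX4 replicate 1 shared 26 and 22 with YFP replicate 1 and 33 and 30 with YFP replicate 2, and HA-SOX4 replicate 2 shared 16 and 24 with YFP replicate 1 and 32 and 30 with YFP replicate 2. Ranked by the mean of the whole region, HA-SOX4 replicate 1 shared 21 and 66 regions with YFP replicate 1 and 54 and 82 with YFP replicate 2, while HA-SOX4 replicate 2 shared 8 and 0 with YFP replicate 1 and 41 and 35 with YFP replicate 2, against 88 and 97 between HA-SOX4 replicates 1 and 2 and 121 and 213 between the YFP replicates. Of the regions shared by both YFP replicates by highest window, 21 and 27 were also among the highest of any HA-SOX4 replicate. The count that independent lists would give was not computed for this set, so whether 21 and 27 exceed it was not determined. With the dyes of the labels, an alternative chosen after the data were seen, the highest regions were shared across the groups as well. The YFP replicates then shared 251 and 308 and HA-SOX4 replicates 1 and 2 shared 249 and 228, while HA-SOX4 replicate 1 shared 187 and 319 with YFP replicate 1 and 225 and 245 with YFP replicate 2, and HA-SOX4 replicate 2 shared 168 and 199 with YFP replicate 1 and 219 and 194 with YFP replicate 2.

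**Figure D4:**
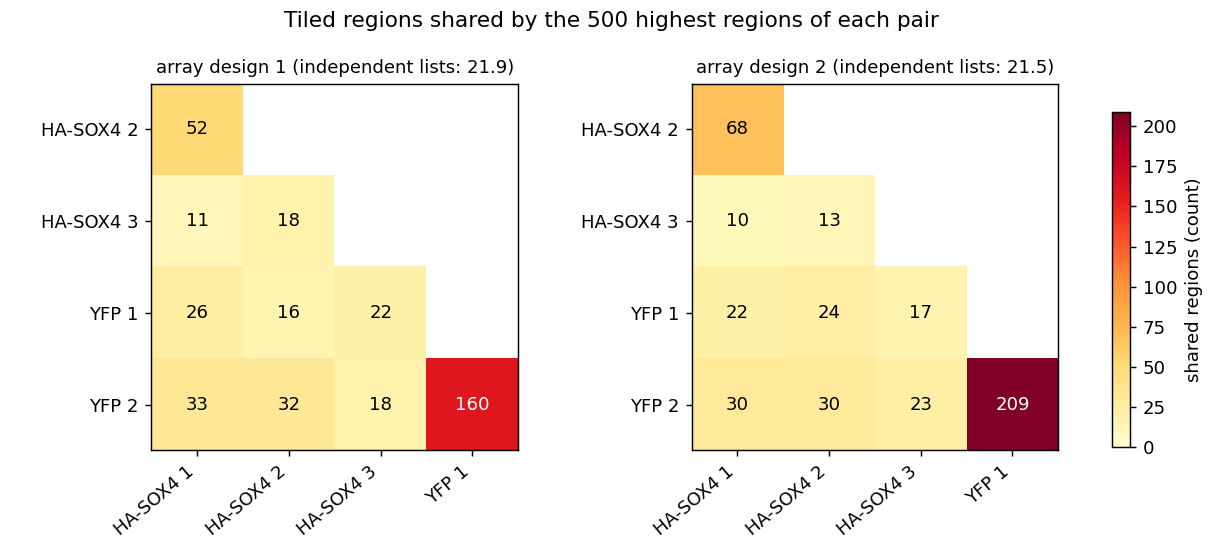
Number of tiled regions (cell value and colour) shared between the 500 regions with the highest window in each pair of biological replicates (x and y axes), with IP and input from the file names, for array design 1 on the left and design 2 on the right. The YFP pair shared 160 and 209 regions and HA-SOX4 replicates 1 and 2 shared 52 and 68, where independent lists would share 21.9 and 21.5.

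Across windows, which are not independent replicates, Pearson's r was 0.694 between the YFP replicates and 0.463 between HA-SOX4 replicates 1 and 2. HA-SOX4 replicate 3 had r = -0.0076 with replicate 1 and r = -0.177 with replicate 2, and with the dyes of the labels these became 0.0076 and 0.177. HA-SOX4 replicate 1 correlated with the YFP replicates at 0.502 and 0.487, and replicate 2 at 0.291 and 0.401.

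By the file names, peaks called in single replicates were nearly all in HA-SOX4 replicate 1, which had 2352 peaks in 2224 regions above a log2 ratio of 3.46, with a median width of 601 bp. HA-SOX4 replicate 2 had 5 peaks above 4.88, on chromosomes 11, 12, 15, 16 and X, and YFP replicate 2 had 62 above 4.11. HA-SOX4 replicate 3 and YFP replicate 1 had 0, because at no cutoff did their upper tail exceed the mirrored lower tail by the margin required. HA-SOX4 replicates 1 and 2 shared 0 peaks, and 0 peaks were in all 3 HA-SOX4 replicates and neither YFP replicate, a count fixed in advance by the 0 peaks of HA-SOX4 replicate 3. Of the 62 peaks of YFP replicate 2, 2 overlapped a peak of HA-SOX4 replicate 1, where 100 random placements gave a mean of 1.92 and at most 6. Loess within arrays gave 5123 peaks in HA-SOX4 replicate 1, 188 in replicate 2, 4 in replicate 3 and 1758 and 1505 in the YFP replicates, with 31 shared by HA-SOX4 replicates 1 and 2. Normexp gave 177 and 369 in the YFP replicates and 7 shared. With the dyes of the labels, an alternative chosen after the data were seen, HA-SOX4 replicates 1, 2 and 3 had 0 peaks each, YFP replicate 1 had 60 and YFP replicate 2 had 0.

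Position was examined in the 14658 of 23047 tiled regions that were 4250 to 4300 bp long. It was counted from the lower HG18 coordinate, without gene strand or transcription start. Taken from the file names, the mean HA-SOX4 minus YFP ratio along these regions was 0.15 in the first 425 bp. It was 0.07 between 1700 and 2125 bp and 0.14 between 3825 and 4250 bp. Between 1700 and 2125 bp, HA-SOX4 averaged -0.01 ± 0.17 (SD, n = 3) and YFP -0.08 ± 0.04 (SD, n = 2), so the difference was smaller than the spread of the HA-SOX4 replicates. The differences in the first and last 425 bp were larger than the SD of the HA-SOX4 replicates, 0.11 and 0.10, as were those of 0.16 between 425 and 850 bp and 0.15 between 3400 and 3825 bp, where the SD was 0.07. They were not tested. Between 1700 and 2125 bp, HA-SOX4 replicates 1 and 2 and both YFP replicates were higher than in the first 425 bp, while HA-SOX4 replicate 3 was lower, at -0.19 against -0.10.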

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

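The mean log2(IP/input) of chromosome 2 was above 0 in every HA-SOX4 replicate (0.09, 0.09 and 0.0034) and below 0 in both YFP replicates (-0.07 and -0.06), a difference of 0.13 in the direction of the file names. With the dyes of the labels, the signs of all but the third HA-SOX4 replicate would turn. This difference was noticed after the values were seen and was not tested, and no explanation of it was examined. The mean difference between HA-SOX4 and YFP was also above 0 on the other chromosomes measured, from 0.004 on X to 0.25 on chromosome 22 among nuclear chromosomes, and 0.46 in mitochondrial DNA, but on none of these did all HA-SOX4 replicates lie above 0 and both YFP replicates below it.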

How the results depend on the processing

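For HA-SOX4 against YFP, 28 of 29 alternatives gave 0 called windows with limma, and the IP channel alone gave 1814 windows in 555 regions. Of the 28, those with another threshold or a minimum difference could only give 0, since the smallest adjusted p of the main limma test was 0.892. Turning replicate 3 alone mirrors IP in Cy5 on every array, and HA-SOX4 against input left YFP out. The 28 are therefore fewer separate tests of HA-SOX4 against YFP. Leaving out each replicate in turn gave 0 windows for that comparison, 0 to 27671 for HA-SOX4 over input, the highest without HA-SOX4 replicate 3, and 0 for YFP over input, where a lone sample was assumed to vary like the others. Normexp correction gave 4 windows for YFP over input. The replicate block gives number 3, which only HA-SOX4 has, a term of its own, so HA-SOX4 replicate 3 did not enter that difference. With a replicate block, 0 windows were called (smallest adjusted p = 0.442, against 0.0133 to 1 over all alternatives), with 7.14% of windows higher and 1.47% lower in HA-SOX4 at an unadjusted p under 0.05, and the deviations of same-numbered replicates correlated at 0.119 and 0.162 in only 2 pairs, too few to show whether the numbers pair the samples.

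Without YFP as a control, the regions on chromosomes 19 and 9 turned to -0.37 and -0.13. With the IP channel alone, those on chromosomes 19, 11 and 9 turned to -0.32, -0.21 and -0.086. With IP in Cy5 on every array, chosen after seeing the data like the turned replicate 3 and single array designs, the regions on chromosomes 19, 11, 7, 9 and 4 turned to -2.86, -2.30, -2.28, -2.68 and -3.16, since it turns both YFP replicates by construction. None of these passed.

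Peak counts moved with background and normalisation. Normexp gave 53 peaks in HA-SOX4 replicate 2, 177 and 369 in the YFP replicates and 7 shared by HA-SOX4 replicates 1 and 2. Loess gave 5123, 188 and 4 in the HA-SOX4 replicates, 1758 and 1505 in YFP and 31 shared. The deposited score gave 36 in HA-SOX4 replicate 2 and 2 shared. With IP in Cy5 on every array, HA-SOX4 replicates 1 and 2 had 0 each and the YFP replicates 60 and 0. Peaks in all 3 HA-SOX4 replicates and no YFP replicate numbered 0 under each of these. Except with loess, this was fixed in advance, since HA-SOX4 replicate 3 alone had 0 peaks, and with loess it had 4. The cause of the changes in peak counts was not tested. Alternatives for gene lists, named genes and the SOX motif were not run. The low share of probes above random probes, 17.5% and 19.9% in HA-SOX4 replicate 3 and 15.7% in YFP replicate 1 on design 1, limits what those ratios can show.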

Other observations

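The test of dye bias was set before its result was seen, whereas the matching tests were extended, and both tests of the YFP regions chosen, after the results were seen.

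HA-SOX4 replicate 3 did not follow replicates 1 and 2, and technical explanations were weighed, since its batch holds no other sample. In the direction of the file names, which gives replicate 3 the opposite dye orientation, dye bias that varies with intensity is argued against, because loess left its correlations with replicates 1 and 2 at 0.0276 and -0.191 (-0.0276 and 0.191 with the dyes of the labels, where no replicate has the opposite orientation). In the 500 regions per design highest in HA-SOX4 replicates 1 and 2 over YFP, replicate 3 lay below regions of like input brightness (-0.63 on design 1 and -0.53 on design 2), which is in line with an exchange of its IP and input files. In regions chosen on HA-SOX4 replicates 1 and 2 alone, however, replicate 3 was at -0.65 and -0.45, YFP replicate 1 at -0.21 and -0.42 and YFP replicate 2 at 0.48 and 0.36 on designs 1 and 2, and matching on the input of replicate 3 itself left -0.22 and -0.07, while matching on its own IP file, the true input under an exchange, left -0.61 and -0.39, against -0.27 and -0.36 in YFP replicate 1. An IP signal near background should have given values near 0 in the first test, but there the inputs of other replicates stood in for its own, so these tests do not tell it and the exchange apart. With replicate 3 turned, as an exchange would, r was 0.0076 with replicate 1 and 0.177 with replicate 2, against 0.463 between replicates 1 and 2. By the file names, mitochondrial DNA in replicate 3, at -1.92, lay below input as in every other replicate, and an exchange would turn it above. These values rest on a single replicate and do not settle the question, and a biological difference of that culture was not tested.

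In the direction of the file names, the promoters highest in YFP were shared between its replicates, 209 of 500 on design 2, which argues against fragments amplified by chance in each IP, and turning both YFP replicates leaves this count but makes these regions the lowest. In that direction, background of the antibody or of the probes common to all IPs is argued against as the whole cause, since in the 200 regions per design highest in both YFP replicates the HA-SOX4 medians on design 2 were 0.19, 0.27 and -0.16, against 2.17 and 2.06 in YFP. Background shared with some HA-SOX4 IPs stays open for part of the regions, since on designs 1 and 2 30% and 27.5% were above 1 in at least 1 HA-SOX4 replicate (18.9% and 16.3% of all windows) and 6% and 1.5% in both replicates 1 and 2 (1.98% and 1.48% of all windows), and the design 1 medians were 0.40, 0.38 and -0.23. With the dyes of the labels, the highest regions were instead shared across groups, 187 and 319 between HA-SOX4 replicate 1 and YFP replicate 1, so a background common to the replicates turned stays open in that direction. DNA or handling shared by both YFP preparations, and a difference between the cell populations, were not tested.

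Mitochondrial DNA, covered by 115 windows, lay below input in every replicate in the direction of the file names, at -0.18, -0.61 and -1.92 in HA-SOX4 and -1.86 and -0.85 in YFP. The difference of 0.46 between the group means was smaller than the SD within either group, 0.91 and 0.71. Among nuclear chromosomes, the lowest YFP means were on chromosomes 22, 19 and 16, at -0.41, -0.36 and -0.32, where HA-SOX4 averaged -0.17, -0.14 and -0.11. The SDs within HA-SOX4 were 0.21, 0.19 and 0.18. HA-SOX4 replicate 1, at -0.41, -0.35 and -0.32, lay between the YFP replicates, and only replicates 2 and 3 lay above both. All 3 chromosomes are on array design 2, which was centred apart from design 1, so this ranking mixes designs. With the dyes of the labels, the mitochondrial values of all replicates but HA-SOX4 replicate 3 would lie above input, and these 3 chromosomes would be the highest nuclear ones in YFP.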
